A study of Mus musculus with 3 samples.

How the data were processed

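Gene expression was measured by RNA sequencing in gastrocnemius and plantaris muscle of male mice. The labels describe 3 groups of mice. Total RNA was pooled within each group, so that each group is represented by 1 library. The young library holds RNA of 3 mice aged 24 weeks. The aged control library holds RNA of 6 mice fed a diet without eicosapentaenoic acid (EPA, an omega-3 fatty acid) for 12 weeks, from 75 to 87 weeks of age. The aged EPA library holds RNA of 6 mice fed a diet with 1 wt% EPA over the same weeks. The strain is given as C57BL/6J for both aged groups and as C57BL/7J for the young group, and the diet of the young mice is not given.

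The processing notes name HISAT2 2.1.0, StringTie 1.3.4d and R 3.5.0 with mouse build GRCm38. The deposited values are CPM (counts scaled to a library total of 1000000) per gene, as the authors calculated them. The tables hold 42258 genes each, of which 21611 had a value above 0 in at least 1 library. The deposited CPM were not made with a single divisor per library. All values above 0 became whole counts when multiplied by 1 of 5 divisors, between 56034275 and 57687235, with a largest distance from a whole number of 3.0268e-09. The divisor differed from gene to gene and, for the same gene, between the tables. The divisor of a gene in 1 table fixed its divisors in the others in 100% of rows. The divisors 57450112, 57687235 and 56034275 lay 0.111%, 0.112% and 0.115% above the count totals recovered for the young, aged control and aged EPA libraries, and the other 2 matched no library of the series. Recovered totals were 57386394 counts for young, 57622886 for aged control and 55969822 for aged EPA. The deposited CPM differed from CPM over each library's own total by between -2.87% and 2.95%, which shifted the log2 change of any gene by at most 0.08 in any of the 3 comparisons.

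Deposited CPM were used as they stood, and values of 63 rows with a repeated gene symbol were summed by symbol. Genes with a mean of at least 1 CPM over the 3 libraries were compared (12966 genes). The change of a gene is the log2 ratio of CPM + 1. Because each group is a single library, no test, p-value or standard error can be given for any difference between groups, and differences are described by their size. Genes at least 2-fold higher or lower were counted. A 95% interval of the ratio of recovered counts (exact Clopper-Pearson, conditional on the sum of both counts) was calculated for named genes. That ratio uses each library's own total and no added 1, so it can differ from the log2 change of CPM + 1. Such intervals and the floor of 3 counts (0.0522 CPM for young, 0.0520 for aged control, 0.0535 for aged EPA) cover counting error only, neither differences between mice nor between library preparations. A gene was counted as having a library alone apart when that library lay at least 2-fold from both others in the same direction and these lay within 1.5-fold of each other.

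Gene lists, 59 in all, were fixed before the data were examined, together with the comparisons, the thresholds and the alternatives apart from 3. For each list the median log2 change of the compared members was placed as a percentile among 10000 random lists of the same size, matched on mean CPM in 20 bins. A list is described as outside the random lists when its percentile was below 2.5 or above 97.5. These percentiles describe the libraries at hand. Members of a list are often regulated together, so random lists are narrower than such lists would be between replicate libraries. Lists with fewer than 3 compared genes were given no percentile, which left 54.

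Named genes followed a rule: the 10 genes with the largest positive and the 10 with the largest negative change in aged control against young and in aged EPA against aged control among genes with a mean of at least 5 CPM, the 5 genes per direction that differed most in opposite directions, and up to 4 members per list. Gene models without a descriptive symbol were only counted. Genes at least 2-fold apart between aged control and young and at least 1.5-fold apart in the opposite direction between aged EPA and aged control were counted. That count was set beside 3 kinds of simulated libraries that share the aged control library, 20 sets of each: counting noise alone, counting noise with a normal spread between libraries (from the median absolute deviation of the changes between aged EPA and aged control), and differences drawn from those observed between aged EPA and aged control.

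Alternatives were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 5 CPM, scaling by the median of ratios and by a trimmed mean of log ratios (TMM), leaving out mitochondrially encoded genes and the 20 most abundant genes, the highest row of a repeated symbol, and 1.5-fold in place of 2-fold. Another 3 were chosen after seeing the data: recovered counts over each library's own total, recovered counts with TMM, and subtraction of the trend of the change with transcript length. That trend was a lowess curve (fraction 0.3) of the log2 change on the log length of the longest protein-coding transcript in GENCODE release M21, or the longest transcript where a gene had none. Gene positions came from the same annotation, which held 42256 of the 42258 gene identifiers. Reads were not available, so counts could not be reassigned between overlapping genes or near-identical copies.

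Simulated counts were made like the aged control and young libraries, with counting noise alone and 200 changed genes among 12980. All counts were recovered in 100% of genes. Of genes set to a 3-fold change, 99% were called at least 2-fold in the right direction, and 0 unchanged genes were called. Of lists drawn from the unchanged genes, 6% fell outside random lists drawn from the same genes. Neither kind was matched on mean CPM, so this rate was set by the construction and does not check the percentiles of the gene lists. The simulated counts held no difference between mice or preparations. The rates for recovered counts and called genes therefore check the calculation and do not give the rate of false calls in the libraries at hand. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. No sample and no deposited column was left out.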

Results

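RNA was sequenced from gastrocnemius and plantaris muscle of young male mice (24 weeks), aged male mice on a diet deprived of EPA (87 weeks, called aged control) and aged male mice on a diet with 1 wt% EPA (87 weeks, called aged EPA). Each of the 3 groups gave 1 library, pooled from 3, 6 and 6 mice. The recovered depth was 57386394 counts for young, 57622886 for aged control and 55969822 for aged EPA, with 19341, 19321 and 19189 genes above 0. No group had a replicate library, so all differences below describe 3 libraries and carry no error between mice or preparations. Where 3 values follow a gene, they are CPM in young, aged control and aged EPA, in this order. Genes of the Y chromosome were present in every library (Ddx3y at 71.00, 66.7 and 61.2 CPM), and Xist, the RNA of the inactive X chromosome, had 4, 0 and 0 counts. Mitochondrially encoded genes took 22.2%, 20.8% and 19.2% of the counts.

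The comparison of aged control with young asks which transcripts differ between muscle of old and young mice. Slow fibre genes, which encode contractile proteins of slow oxidative fibres, were higher in the aged control library (median log2 change 0.49, above all 10000 random lists), with 9 of 12 members higher. Myh7, the slow myosin heavy chain, stood at 66.4 CPM in young and 178 CPM in aged control (log2 1.41, log2 count ratio 1.449, 95% counting interval 1.395 to 1.504). PPAR target genes, which handle fatty acids in muscle, were lower in aged control (median -0.43, below all random lists), with 19 of 20 members lower. Haemoglobin transcripts were lower (Hba-a1 at 479 against 180.0 CPM), and antibody transcripts were higher (Igkc, the kappa light chain, at 0.728 against 8.02 CPM).

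Of 12966 genes compared, 116 were at least 2-fold higher and 109 at least 2-fold lower in aged control than in young, together 1.74% of the genes, and 94.8% lay within 1.5-fold. Among genes with a descriptive symbol and a mean of at least 5 CPM, the largest positive change was that of Sh3pxd2a, which encodes an adaptor protein of podosomes (ENSMUSG00000053617, chromosome 19, 47260174 to 47464401 on GRCm38), at 4.07, 72.8 and 70.2 CPM (log2 3.86, log2 count ratio 4.118, 95% counting interval 3.927 to 4.314). Carns1, which encodes carnosine synthase (chromosome 19, 4164324 to 4175479), was listed at 0 in young and at 11.4 and 13.7 CPM in aged control and aged EPA. Gas7 stood at 1.89, 22.5 and 2.34 CPM, Ahdc1 at 4.23, 24.4 and 3.85 CPM and Ablim1, which encodes an actin-binding protein, at 17.7, 75.4 and 15.8 CPM, so that these 3 were high in the aged control library alone. The Polycomb gene Phc3 stood at 4.48, 24.7 and 22.8 CPM and the ubiquitin ligase gene Rnf170 at 3.93, 19.8 and 20.9 CPM. Among zinc finger genes, Repin1 stood at 2.66, 15.8 and 17.4 CPM and Zbtb4 at 8.91, 44.3 and 42.4 CPM.

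Among the same genes, the 10 largest negative changes in this comparison belonged mostly to genes low in the aged control library alone. Cacng6 (chromosome 7, 3424195 to 3435667) and Cacng7 (chromosome 7, 3332955 to 3368221), neighbours that encode gamma subunits of calcium channels, were listed at 0 in aged control, with 61.1 and 14.4 CPM in young and 66.4 and 13.8 CPM in aged EPA. Zdhhc8, which encodes a palmitoyltransferase, was also listed at 0 in aged control, with 19.9 CPM in young and 23.3 CPM in aged EPA. Reads were not available, so it is not known whether the zeros of Cacng6, Cacng7 and Zdhhc8, or those of Carns1 in young and H2ac18 in aged EPA, arose in the counting step. The transcription factor gene Vezf1 (chromosome 11, 88068279 to 88084729) stood at 49.6, 0.212 and 54.7 CPM (log2 -5.38) and Sp1, another transcription factor gene, at 29.2, 1.72 and 23.5 CPM (log2 -3.47). Pcmt1, which encodes an enzyme that repairs damaged aspartyl residues in proteins, stood at 43.7, 5.53 and 50.7 CPM. Zfp322a stood at 11.3, 1.71 and 8.08 CPM, Nkapd1 at 11.6, 1.81 and 9.96 CPM and Fsd1l at 12.01, 1.397 and 3.52 CPM. Cd63-ps, a pseudogene whose reads may also match Cd63, stood at 12.8, 0.553 and 12.2 CPM and its assignment is uncertain.

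Other contractile genes differed along with the slow fibre list. The slow troponins Tnni1, Tnnt1 and Tnnc1 stood at 18.5, 38.97 and 29.7 CPM, 36.9, 70.2 and 52.5 CPM and 25.3, 44.1 and 36.1 CPM. The fast myosin heavy chains Myh2, Myh1 and Myh4 were also higher in aged control, at 1638, 2051 and 1578 CPM, 1675, 2447 and 2118 CPM and 25129.7, 32200.5 and 29432 CPM, while the fast fibre list as a whole had a median of 0.12 (percentile 94.6). Sarcomere and Z-disc genes had a median of 0.26 (percentile 99.99), with 14 of 18 members higher, among them Flnc, which encodes filamin C, at 514 against 738 CPM and the M-band gene Myom2 at 759 against 1092 CPM. Embryonic and perinatal contractile genes had a median of 0.04, with Actc1, the cardiac actin, at 81.8 against 48.5 CPM.

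**Figure D1:**
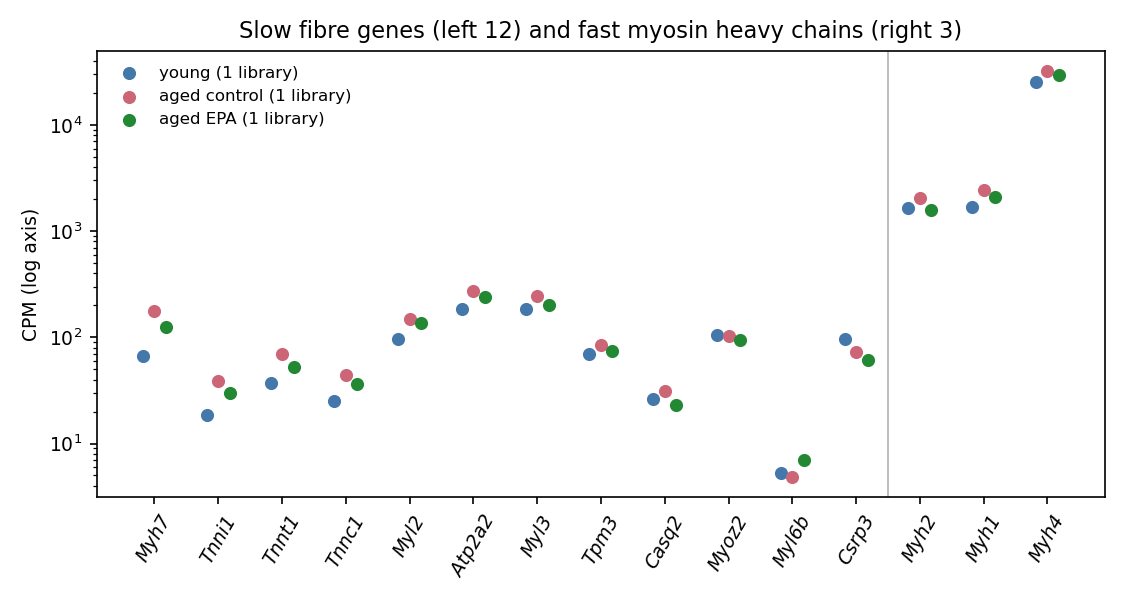
CPM (log axis) of the 12 slow fibre genes and 3 fast myosin heavy chains in the young, aged control and aged EPA libraries, 1 point per library. Myh7 stood at 66.4, 178 and 126 CPM in this order, and 9 of the 12 slow fibre genes were highest in aged control.

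Some lists of energy metabolism were lower in aged control, while tricarboxylic acid cycle (median 0.02), glycolysis and glycogen (0.00), insulin signalling (0.01), PGC-1 (-0.04) and mitochondrially encoded genes (-0.11) lay inside the random lists. PPAR targets included the lipid droplet gene Plin5 at 25.2, 14.2 and 18.5 CPM, the acyl-CoA thioesterase gene Acot2 at 44.1, 25.1 and 28.8 CPM, Fabp3, which carries fatty acids in the cell, at 561, 373 and 415 CPM, and Pdk4, a brake on glucose oxidation, at 1519.8, 1019 and 1051 CPM. Fatty acid oxidation genes had a median of -0.20 with 18 of 20 members lower. Complex I genes of the respiratory chain had a median of -0.20 with 34 of 36 lower (Ndufc1 at 98.9, 56.1 and 80.5 CPM), complex II to V genes a median of -0.23 with 35 of 39 lower (Cox4i1 at 348, 229.8 and 349.6 CPM), and cytosolic ribosomal protein genes a median of -0.27 with 44 of 46 lower (Rpl41 at 210.2, 136 and 144 CPM). Antioxidant genes had a median of -0.22 with 15 of 18 lower, although Srxn1, which encodes sulfiredoxin, was higher in both aged libraries at 8.202, 35.5 and 31.9 CPM. Amino acid and creatine metabolism genes had a median of -0.18 (percentile 0.7), with the spermine oxidase gene Smox at 243, 145 and 171 CPM. Proteasome genes had a median of -0.12 (percentile 0.2100) with 21 of 25 lower.

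Among genes that respond to stimulation and among markers of other cells, several lists lay outside the random lists. Immediate early genes were higher (median 0.27, 16 of 18 members), with Fos at 25.8, 70.96 and 52.5 CPM, Egr1 at 32.5, 61.1 and 56.6 CPM and Dusp1 at 95.02, 165 and 146 CPM. B and plasma cell markers had a median of 0.95 over 5 compared genes (0.15 to 1.98 over the alternatives), with Ighg2c at 3.42, 13.8 and 16.3 CPM and Ighm at 148, 211 and 222 CPM. Complement genes had a median of 0.12 (percentile 97.6) and tendon markers a median of 0.27 (percentile 99.8), with Tnmd at 5.23, 9.51 and 7.66 CPM. Red blood cell markers were lower (median -1.40). Adipocyte markers were lower (median -0.36, -0.51 to -0.20 over the alternatives, 12 of 13 members), with adipsin, Cfd, at 109.7, 59.1 and 85.3 CPM. Endothelial markers were lower (median -0.29, 10 of 12 members), with the tight junction gene Cldn5 at 24.1, 9.22 and 13.00 CPM. Collagen and matrix genes had a median of -0.10 (percentile 2.01), with Col3a1 at 217, 150.01 and 110.0 CPM. Nuclear retained noncoding RNAs had a median of -0.26 (percentile 1.81), with Meg3 at 9.67, 5.98 and 5.35 CPM.

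In all, 19 of 54 lists lay outside the random lists in this comparison, where 2.7 would be the number for independent lists of unrelated genes. The change also went with transcript length (Spearman's rho 0.29 across 12966 genes, which are not independent replicates), and with that trend subtracted the medians were -0.14 for ribosomal protein, -0.09 for complex I and -0.07 for complex II to V genes, all still outside, and -0.04 for proteasome genes, no longer outside (percentile 14.3). Another 5 lists lay outside only after subtraction, with medians of 0.13 for fast fibre, 0.12 for calcium handling, -0.09 for autophagy and lysosome, -0.11 for glucocorticoid-responsive and 0.18 for MHC class II genes.

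**Figure D2:**
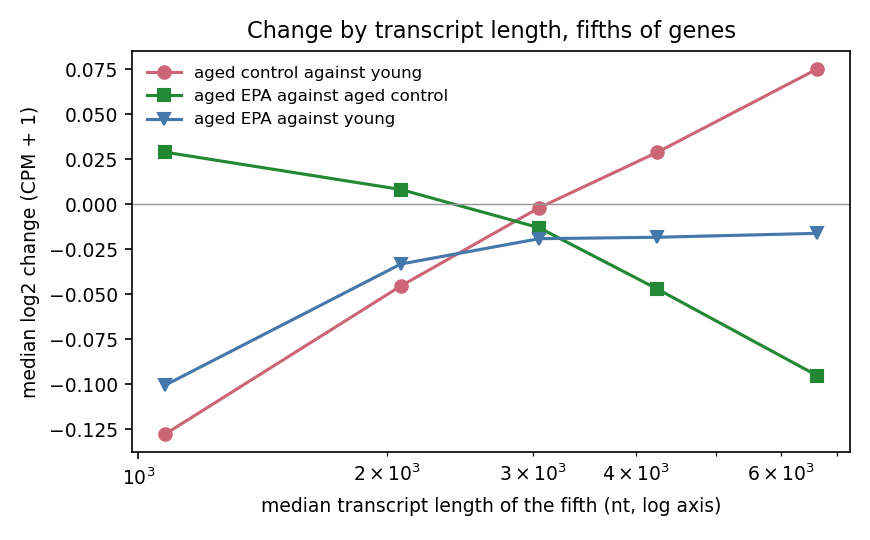
Median log2 change of CPM + 1 in 5 equal groups of genes by transcript length (nucleotides, log axis) for the 3 comparisons. Aged control against young went from -0.13 in the shortest to 0.08 in the longest group, and aged EPA against aged control from 0.03 to -0.10.

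The comparison of aged EPA with aged control asks what differs in old muscle with EPA in the diet. Slow fibre genes were lower in the aged EPA library (median log2 change -0.26, below all random lists), with 11 of 12 members lower and Myh7 at 178 CPM in aged control and 126 CPM in aged EPA. Collagen and matrix genes were lower (median -0.17, 20 of 22 members), with Col3a1 at 150.01 against 110.0 CPM and the matricellular gene Postn at 12.9 against 8.56 CPM. Adipocyte markers were higher (median 0.20, 12 of 13 members), with Cfd at 59.1 against 85.3 CPM. Schwann cell and nerve markers were higher (median 0.20, 0.10 to 0.24 over the alternatives, 11 of 12 members). Antigen presentation genes of MHC class I were slightly higher (median 0.13, 13 of 15 members), with H2-Q4 at 14.2 against 18.2 CPM.

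Of the 12966 genes, 90 were at least 2-fold higher and 83 at least 2-fold lower in aged EPA than in aged control (1.33%), and 96.4% lay within 1.5-fold. Of the 10 named genes with the largest positive change, Cacng6, Vezf1, Zdhhc8, Cacng7, Sp1, Cd63-ps and Pcmt1 are those that were low or at 0 in the aged control library alone. The other 3 were highest in aged EPA. Rsc1a1 (ENSMUSG00000040715, chromosome 4, 141683851 to 141685599), which lies within the gene Ddi2 so that the assignment of its reads is uncertain, stood at 0.191, 0.286 and 34.04 CPM (log2 4.77). The zinc finger gene Zc3h11a stood at 17.9, 11.2 and 83.8 CPM (log2 2.80, log2 count ratio 2.973, 95% counting interval 2.853 to 3.095), and Mgat1, which encodes an enzyme of N-glycan synthesis, at 3.87, 6.701 and 32.5 CPM (log2 2.12).

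Among the 10 named genes with the largest negative change, Gas7, Ahdc1 and Ablim1 are those that were high in aged control alone, and the histone gene H2ac18 was listed at 0 in aged EPA with 18.95 and 9.24 CPM in young and aged control. Gpr146, which encodes a receptor, stood at 66.4, 54.7 and 10.97 CPM (log2 -2.22), and Stx17, which encodes a syntaxin of autophagosome fusion, at 30.6, 30.1 and 7.09 CPM. Ago1, an Argonaute gene of RNA silencing, stood at 11.7, 14.96 and 3.69 CPM, Mier1 at 9.101, 22.3 and 5.396 CPM and Tmem8b at 16.9, 19.6 and 6.42 CPM. Rps27rt, a retroposed copy of Rps27, stood at 61.5, 58.2 and 10.9 CPM while Rps27 itself stood at 120.4, 69.6 and 115 CPM. Reads of H2ac18, of Rps27rt and of other ribosomal protein genes can match near-identical copies, so their assignment is uncertain.

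Further lists lay outside the random lists in aged EPA against aged control. B and plasma cell markers were higher (median 0.23, 0.07 to 0.26 over the alternatives, 5 of 5 members), with Xbp1, a transcription factor of plasma cells that muscle also expresses, at 32.3, 31.4 and 78.1 CPM. Complement genes were higher (median 0.10, 11 of 15 members, C4b at 29.6, 40.3 and 50.4 CPM). Smooth muscle and pericyte markers were lower in all 12 members (median -0.18, with Pdgfrb at 52.3, 47.4 and 38.9 CPM), mitochondrially encoded genes were lower in 12 of 13 members (median -0.16, mt-Nd6 at 6449, 6169 and 3698 CPM), myokine genes in 10 of 10 (median -0.16, percentile 1.55, Ostn at 30.2, 66.5 and 56.5 CPM), and fatty acid synthesis genes in 13 of 18 (median -0.13, percentile 1.31, Fasn at 39.6, 42.4 and 32.3 CPM). PPAR targets, the textbook targets of fatty acids, had a median of 0.05 (percentile 95.4), with Acsl1, which activates fatty acids, at 377, 327 and 126 CPM. Fatty acid oxidation genes had a median of -0.01, complex II to V genes 0.01, endothelial markers -0.07 and red blood cell markers 0.03, all inside the random lists.

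In all, 17 of 54 lists lay outside the random lists. Here the change with transcript length was opposite to that with age (rho -0.22), and 6 lists were no longer outside with that trend subtracted: fast fibre genes (median 0.09 before, 0.04 after), sarcomere and Z-disc genes (-0.10 before, -0.01 after), neuromuscular junction genes (-0.15 before, -0.07 after), autophagy and lysosome genes (0.05 before, 0.04 after), complex I genes (0.04 before, -0.01 after) and ribosomal protein genes (0.06 before, 0.01 after). Another 3 lists lay outside only after subtraction: PPAR targets (0.05 before, 0.06 after, percentile 98.9), immediate early genes (-0.10 before, -0.12 after) and embryonic and perinatal contractile genes (-0.21 before, -0.25 after). The change also went with GC content (rho 0.23). With that trend subtracted instead, slow fibre (median -0.26), sarcomere and Z-disc (-0.10) and ribosomal protein genes (0.06) lay outside. Most other lists were not corrected for it.

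**Figure D3:**
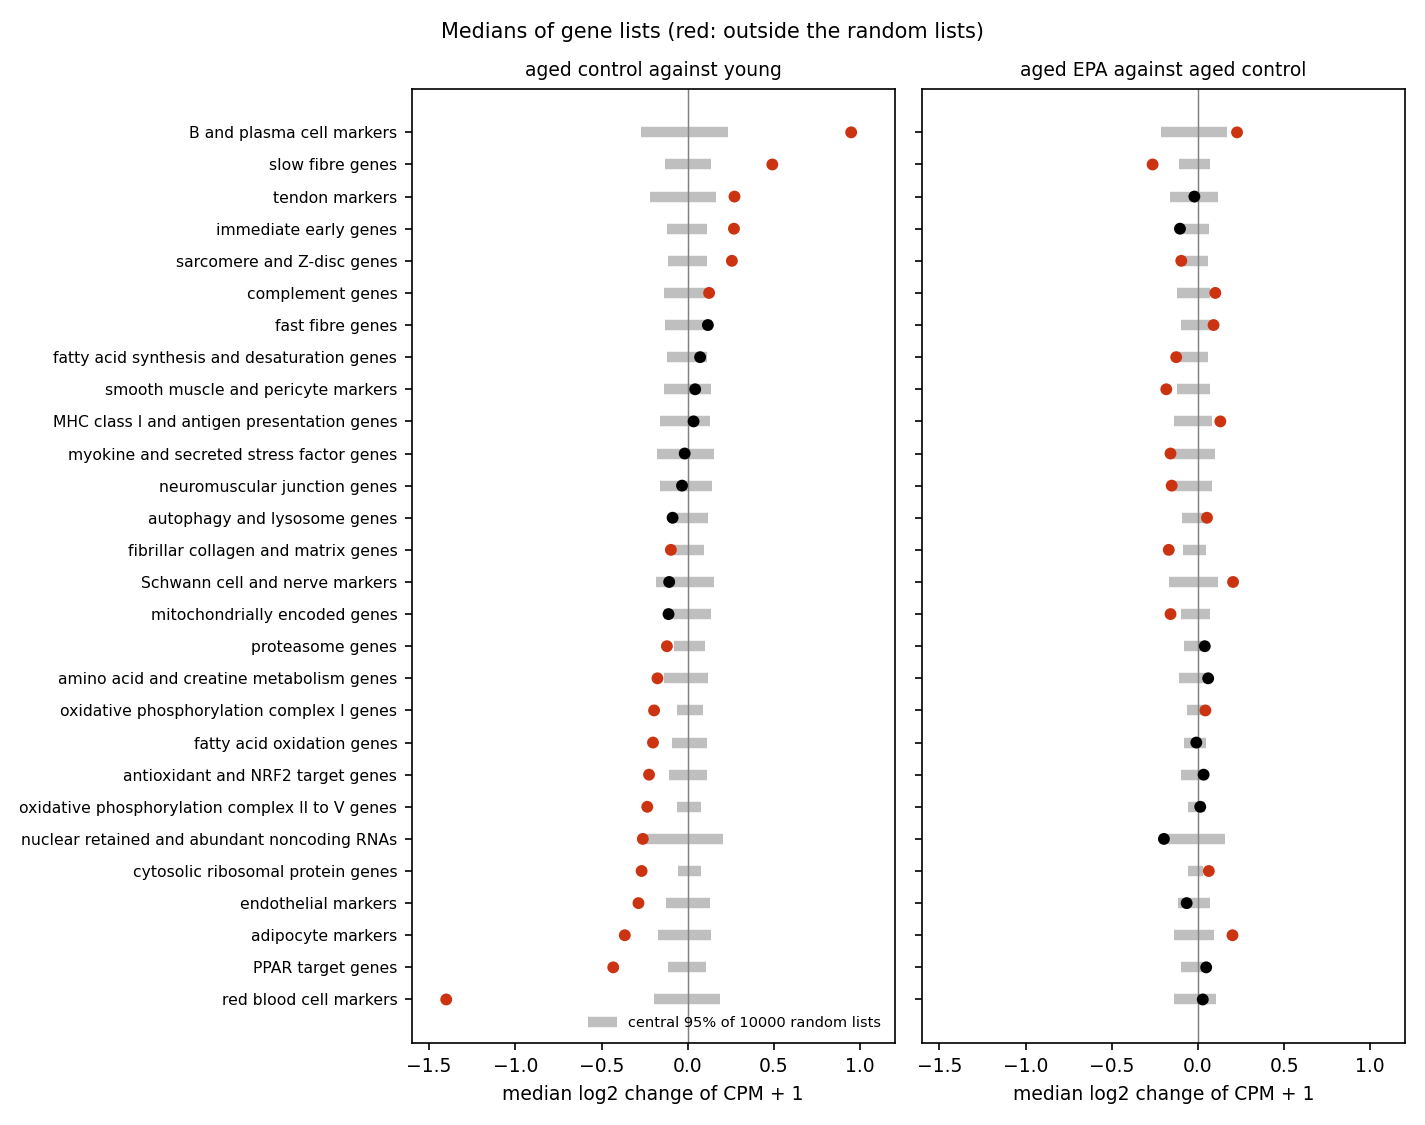
Median log2 change of CPM + 1 of the gene lists outside the random lists in aged control against young (left) or aged EPA against aged control (right); points are medians, red when outside, and grey bars span the central 95% of 10000 random lists. Slow fibre genes had medians of 0.49 (left) and -0.26 (right), and adipocyte markers -0.36 and 0.20.

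Genes that differ in opposite directions with age and with EPA do not by themselves show whether the EPA library lies closer to the young library than the aged control does. At least 2-fold from young were 225 genes in aged control and 208 in aged EPA, and at least 1.5-fold 679 and 695. Spearman's rho with the young library across genes was 0.982 for aged control and 0.983 for aged EPA. Gas7, Ahdc1, Ablim1, Rab6a and Pafah1b1 were the named genes higher in aged control than in both others. Rab6a, which encodes a GTPase of Golgi transport, stood at 35.1, 99.01 and 36.9 CPM, and Pafah1b1, which encodes a dynein regulator, at 49.5, 138 and 55.6 CPM. Cacng6, Vezf1, Zdhhc8, Cacng7 and Sp1 were the named genes lower in aged control than in both others. Of the gene lists outside the random lists in both comparisons, 5 had opposite medians: slow fibre, sarcomere and Z-disc, complex I, ribosomal protein and adipocyte genes. The others had medians in the same direction with age and with EPA, further from young. They were B and plasma cell markers (0.95 and 0.23), complement genes (0.12 and 0.10) and collagen and matrix genes (-0.10 and -0.17). With the length trend subtracted, sarcomere, complex I and ribosomal protein genes lay inside the random lists in aged EPA against aged control.

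The count was 40 genes at least 2-fold higher in aged control than in young and at least 1.5-fold lower in aged EPA than in aged control, and 67 genes in the reverse pair, together 107. Same-direction pairs held 1 and 2 genes. The aged control library enters both ratios with opposite signs, and the correlation across genes between both changes was -0.50 in the data. It was -0.49 or -0.50 in all 3 kinds of simulated libraries, so it says nothing about the size of the noise. The covariance, which depends on that size, was -0.0545 in the data. In simulated libraries it was -0.0032 with counting noise alone, -0.0159 with a normal spread added and -0.0487 with differences drawn from those observed. Simulated libraries gave 0 genes in opposite directions both with counting noise alone and with counting noise and a normal spread between libraries. With differences drawn from those observed between aged EPA and aged control the mean was 92.85 (76 to 117 over 20 simulations), but these carry any difference between the groups, so the number that noise between mice or preparations would give is not known. By the rule for a library alone apart, the count was 72 genes for aged control, 68 for aged EPA and 88 for young.

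**Figure D4:**
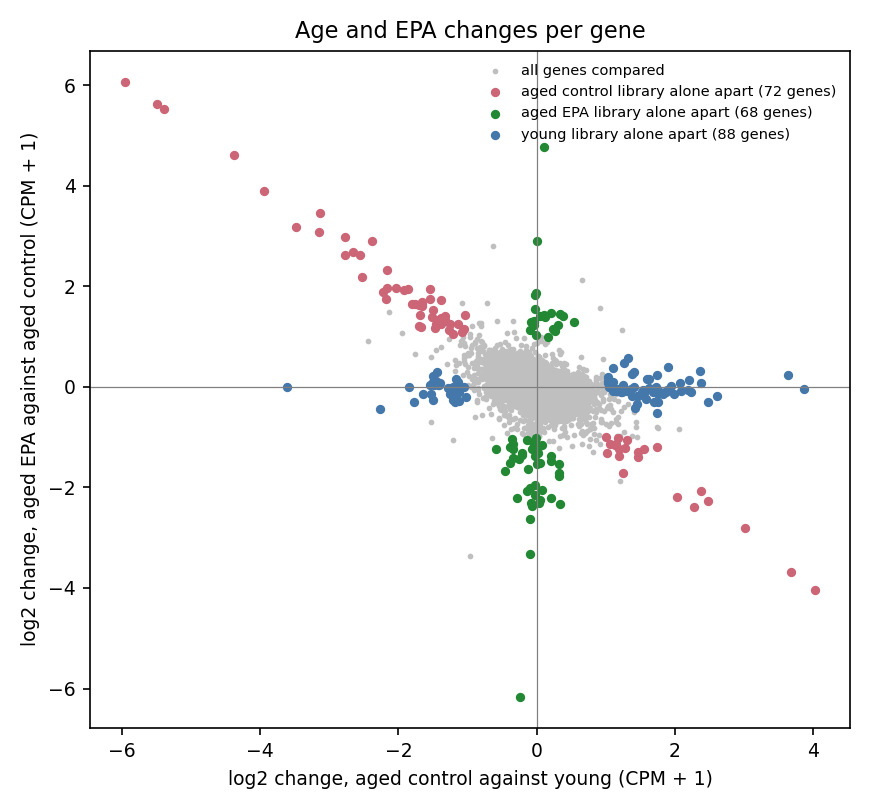
Log2 change of CPM + 1 in aged control against young (horizontal) and in aged EPA against aged control (vertical), 1 point per gene, with genes coloured by the library that was alone apart. The 72 genes with aged control apart lie along the falling diagonal, and 68 genes with aged EPA apart lie near the vertical axis.

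The comparison of aged EPA with young asks which differences from young muscle were present in the EPA library as well. Sh3pxd2a, Phc3, Repin1, Zbtb4, Rnf170 and Srxn1 had similar CPM in both aged libraries, as given above. Slow fibre genes were higher in aged EPA than in young (median 0.37), with Tnni1 at 18.5 against 29.7 CPM, and immediate early genes were higher (median 0.35, 17 of 18 members), with Fos at 25.8 against 52.5 CPM. PPAR targets (median -0.42), red blood cell markers (-1.33), ribosomal protein genes (-0.25), fatty acid oxidation genes (-0.18) and endothelial markers (-0.35, 12 of 12 members) were lower. Adipocyte markers, in contrast to their median of -0.36 in aged control, had a median of -0.05 (percentile 39.1).

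Between these libraries 104 genes were at least 2-fold higher and 104 at least 2-fold lower in aged EPA (1.60%), with 94.6% within 1.5-fold. B and plasma cell markers were higher, with a median of 1.25 (0.47 to 2.22 over the alternatives, 5 of 5 members). That median is the value of Xbp1, which is not an antibody gene. Also higher were MHC class I genes (median 0.20, 14 of 15, H2-Q7 at 4.86, 6.28 and 8.098 CPM), MHC class II genes (0.19, 5 of 8, Cd74 at 125, 141 and 157 CPM) and complement genes (0.22, 13 of 15). Tendon markers had a median of 0.26 and sarcomere and Z-disc genes 0.19. Schwann cell markers had a median of 0.17 (0.08 to 0.23 over the alternatives), with Pmp22, a myelin gene, at 42.3, 64.6 and 69.00 CPM. Collagen and matrix genes were lower (median -0.24, 19 of 22 members, Col1a1 at 171, 134 and 107 CPM), as were heat shock genes (-0.22, Hspa1a at 25.9, 15.3 and 14.5 CPM), glucocorticoid-responsive genes (-0.26, with the metallothioneins Mt1 at 50.1, 24.1 and 20.9 CPM and Mt2 at 43.8, 19.6 and 16.1 CPM), and muscle stem cell and myogenic genes (-0.25, with Heyl at 15.8, 10.99 and 10.9 CPM). Mitochondrially encoded genes were lower in all 13 members (median -0.23). Also lower were complex I (-0.16), complex II to V (-0.18), antioxidant (-0.16), myokine (-0.21) and proteasome genes (-0.11) and nuclear retained noncoding RNAs (-0.42).

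In all, 25 of 54 lists lay outside the random lists in aged EPA against young. Here the change went with GC content (rho 0.16) as well as with transcript length. With the length trend subtracted (rho 0.12 in this comparison) proteasome genes were no longer outside, with a median of -0.06, complex I and complex II to V genes stayed outside with medians of -0.10 and -0.09, and 3 lists lay outside only then, with medians of 0.14 for fast fibre genes, -0.14 for amino acid and creatine metabolism genes and 0.10 for macrophage markers.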

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

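The alternatives with recovered counts and with the length trend subtracted were chosen only after the results were seen; the others were fixed before. No paired analysis was possible because the labels link no mice across groups, and no replicate could be left out because each group has 1 library. Counts of genes past the threshold stayed within 1.5 times their main value without a filter on low values, under both scalings, without the most abundant genes, with the highest row of a repeated symbol, with recovered counts and with the length trend subtracted. They moved further under the other 4. With a pseudocount of 0.1 the counts at least 2-fold apart were 346 for aged control against young (173 lower), 264 for aged EPA against aged control (135 lower), 348 for aged EPA against young (166 higher, 182 lower) and 164 for opposite directions. With a pseudocount of 5 they were 104 (57 higher, 47 lower), 78 (47 higher, 31 lower), 94 (52 higher, 42 lower) and 48. With a mean of at least 5 CPM they were 68 lower in the first, 111 (58 higher, 53 lower) in the second, 138 (65 lower) in the third and 67 in opposite directions, since fewer genes were compared. At 1.5-fold they were 679 (349 higher, 330 lower), 467 (219 higher, 248 lower), 695 (311 higher, 384 lower) and 190, by the looser threshold itself. Of the list medians outside the random lists, 1 changed sign: complex I genes in aged EPA against aged control, from 0.04 to -0.0115 with the length trend subtracted, an alternative that removes what short transcripts share. Of all list medians under all alternatives, 1645 values were classed as moved by less than their spread and 133 as moved further. A change of sign was classed apart only for medians outside the random lists, which is the 1 value given above. Of the 101 medians inside the random lists, 42 changed sign under at least 1 alternative (103 of 1110 values), and the largest of these was 0.20 from 0. The slow fibre median ranged from 0.48 to 0.53 for aged control against young and from -0.32 to -0.20 for aged EPA against aged control, and that of the B and plasma cell markers, with 5 compared genes, from 0.15 to 1.98 for aged control against young, from 0.07 to 0.26 for aged EPA against aged control and from 0.47 to 2.22 for aged EPA against young. That of the nuclear retained noncoding RNAs ranged from -0.45 to -0.11 for aged control against young and from -0.47 to -0.11 for aged EPA against young, nearest to 0 without a filter on low values. Of 61 list medians outside the random lists, 29 left the range of 1.5 times their main value under at least 1 alternative. No scaling moved the median of all genes by more than 0.1. Depth limits genes near the floor of 3 counts, and the single library per group limits every result.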

Other observations

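The tests of overlapping genes, of an effect of EPA that returns age changes, of dissected slow muscle, of blood and of length as the whole cause were chosen only after the results were seen, as were all alternatives that use recovered counts or subtract the length trend. The bounds in the tests of blood and of noise were also revised after their values were seen.

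Ubiquitin ligase and FoxO genes, denervation-responsive genes and calcium handling genes lay inside the random lists in the 3 comparisons, with medians for aged control against young and aged EPA against aged control of 0.03 and -0.06 for the ubiquitin ligase list, -0.04 and -0.11 for the denervation list, and 0.12 and -0.05 for the calcium list. Single members differed more: Trim63, the atrophy ligase MuRF1, stood at 459.5, 320.4 and 347 CPM, the mitochondrial ligase gene Mul1 at 35.1, 19.4 and 34.3 CPM, and Ddit4, an inhibitor of mTOR signalling, at 38.2, 51.3 and 31.6 CPM. Glycolysis and glycogen genes had medians of 0.00 and 0.00, although the glycogen synthase gene Gys1 stood at 278, 537 and 329.5 CPM and Gapdh, which has many pseudogene copies, at 642, 372 and 251 CPM. Tricarboxylic acid cycle genes had medians of 0.02 and -0.01, insulin signalling genes 0.01 and -0.07 (Tbc1d1 at 43.7, 68.2 and 67.3 CPM), PGC-1 and mitochondrial biogenesis genes -0.04 and -0.01 (Ppara at 6.64, 11.1 and 6.997 CPM), cholesterol synthesis genes 0.03 and -0.09, and eicosanoid and fatty acid receptor genes 0.07 and -0.03 (Ptgs1, a cyclooxygenase, at 5.71, 6.03 and 4.86 CPM). Circadian clock genes had medians of 0.07 and -0.02 over members that went both ways, with Per2 at 16.9, 30.02 and 25.4 CPM, Dbp at 70.3, 109 and 116 CPM and Arntl, which encodes BMAL1, at 25.5, 15.9 and 14.01 CPM; the labels give no time of day for the dissections.

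Macrophage markers had medians of -0.03 and 0.03 (Cd163 at 26.8, 35.8 and 36.7 CPM), interferon-stimulated genes 0.07 and -0.04, and inflammatory cytokine genes 0.01 and -0.15. Fibro-adipogenic progenitor markers had medians of 0.03 and -0.03, with Ly6a, also called Sca-1, at 60.7, 21.3 and 49.3 CPM. Matrix remodelling genes had medians of 0.09 and -0.02, with Ccn2, connective tissue growth factor, at 39.2, 71.7 and 50.6 CPM. Senescence genes had medians of -0.07 and 0.05 (Cdkn1a at 34.6, 29.7 and 29.9 CPM), unfolded protein response genes -0.10 and -0.09, brown adipocyte markers 0.20 and -0.20, histone genes without a poly(A) tail 0.00 and 0.04, sex-linked genes -0.05 and -0.10, and reference genes -0.02 and -0.04. Lists with fewer than 3 compared genes were represented by Csf3r for neutrophils (log2 0.94 and -0.16), Trf for liver and plasma proteins (0.16 and 0.25), Myh2 for type IIA fibres (0.32 and -0.38), 2 epidermis genes (medians -0.26 and 0.28) and 0 T and NK cell genes. Of the 7 compared red blood cell genes, 5 were at least 1.5-fold lower in both aged libraries, while Bpgm, at 69.9, 68.5 and 66.8 CPM, and Fech, at 141, 148 and 147 CPM, were level. Bpgm and Fech are expressed in other cells as well, so their values do not decide whether less blood was left in the aged tissue. Less blood cannot be told apart from lower expression in blood cells, because no separate measure of blood content is at hand.

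In 72 genes the aged control library lay apart from both others, among them Vezf1, Sp1 and Gas7. The divisors that differ between genes are argued against as the cause, because they shifted the log2 change of any gene by at most 0.08. Only genes near the threshold could move by that much, and 95.8% of the 72 genes stayed apart with recovered counts. Of the 72 genes, 42 overlapped no other gene above 0. Counts moved between genes that overlap are argued against as the general cause in the other 30. The overlapping genes moved the opposite way by 50% to 150% of the change in CPM in only 3 of them. Such a move stays open for these 3, Gemin4, Gm20716 and Lime1, which are named after their values were seen. Overlapping genes of Xrcc3 and Pcdhgb1 moved the opposite way by more (175% and 255%), and abundant overlapping genes can hide a move. Reads lost from both genes in the counting step would leave no such trace and stay open. Adding the counts of overlapping genes left 14 of the 30 apart, which decides nothing, since abundant overlapping genes dilute any change. Noise of a single library that enters both ratios cannot be told apart from a difference between the groups: 72 genes for aged control against 68 for aged EPA is a ratio of 1.059. That ratio ran from 0.969 to 1.17 under 11 alternatives but reached 1.5 (39 against 26 genes) with a pseudocount of 5. Among the 11, the 1.5-fold alternative did not alter this rule and repeats the main counts. The highest row of a repeated symbol gave the same counts as well. An effect of EPA that returns age changes towards the young level cannot be told apart from such noise either, because each group has 1 library and the ratio of 72 genes for aged control to 88 for young, 0.818, lies between the bounds of its test. Gene lists (5 with aged control beyond both others, 7 with aged EPA beyond both others) and the simulations were tried before and did not decide it. A difference between mice or preparations in single transcripts stays open and untested, since each group has 1 library.

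Ribosomal protein and oxidative phosphorylation genes, 121 together, were lower in aged control than in young with a median of -0.24, and these have short transcripts. A trend of the change with transcript length could account for more than 50% of that difference, since 40.7% of it was left after the trend of all other genes was subtracted. As the whole cause, the trend is argued against by the median left, -0.10, which lay below all 10000 random lists corrected alike. Random lists were matched on mean CPM and not on length, so a poor fit of the trend among short transcripts is not excluded. The change hardly went with GC content in this comparison (rho -0.02), so subtracting that trend could remove little, and 93.6% was left. A trend with GC content is thus argued against in aged control against young only. A difference in RNA integrity or library preparation between the pools, and age, diet or the strain as labelled, stay open and untested.

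Slow fibre genes were highest in the aged control library. A trend with transcript length is argued against, since 110.8% of the median change was left after its subtraction. More slow muscle in the dissected piece of the aged control cannot be told apart from a difference in the fibres themselves: 9 of the 12 genes were higher in aged control than in both other libraries, and a single pool per group confounds the piece with the group. Age, diet and, against young, the strain as labelled stay open and untested.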
